A study of Mus musculus with 6 samples.

How the data were processed

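Total RNA of 6 cultures of mouse lung fibroblasts, 3 from Mmp19 knockout and 3 from wild-type mice, was labelled with Cy3 from 0.5 µg per sample and hybridised to one-colour Agilent arrays, per the labels' protocols. Groups and replicate numbers come from the sample titles, and the series text describes independent experiments.

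The deposited scanner tables hold spot intensities: per the file headers, Agilent Feature Extraction version 10.7.3.1 gave a processed intensity with background subtracted, the median intensity of each spot and of its local background, and flags for each spot. The submitters' processing notes name version 9.1 of that software, and the difference between them is not settled here. The array design was annotated on mouse build mm9, per the file headers. The authors also deposited a table of log2 values for 35844 probes; its column medians ran from 5.51 to 5.76. Each column correlated with the log2 processed signal of its own array at 0.996 or more and with every other array at 0.988 or less. How the authors normalized that table between arrays is not given in the sources used here, so its centring stays unknown; it served as an alternative only.

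Control spots were left out, and repeated spots of 1 probe were averaged after outlier flags were removed, which left 55681 probes from 59305 spots; 259 of them lacked a value on at least 1 array. Each array's 75th percentile of the log2 processed intensity was subtracted. Probes were tested if flagged well above background on all 3 arrays of at least 1 group (24214 probes, 43.5%). No spot was saturated. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Changes are log2 differences, knockout minus wild type, with standard errors from the moderated fit. For a probe not well above background on any array of 1 group, a fold is given as "at least": the mean of the bright group was set against the mean, over the dim group's arrays, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array.

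Scanner tables carry accessions and no gene symbols, so probes were named by unversioned RefSeq accession through an annotation table of the assembly GRCm38.p6; 26413 of 55681 probes (47.4%) matched, and the others are unnamed here. No coordinates were taken from it, only names, chromosome membership and gene order. A gene was represented by its tested probe with the highest mean over all arrays, giving 12470 genes. Of 598 genes past the threshold 112 had several tested probes, of which 60 had all probes past it and 7 had a probe of opposite sign.

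The lists of genes and the choices of test and alternatives were fixed before the data were examined. There were 43 lists, of which 40 had at least 5 measured genes and were tested with camera of limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Genes that lacked a value on some array (32 of all genes) were counted as measured but left out of the list tests, which need complete values. Camera with an estimated correlation and fry stood beside it. When the correlation is estimated, camera also takes its degrees of freedom from the few arrays instead of from the genes, which raises p by itself. The list of Y-linked genes and Xist was given as values only; lists of B and plasma cell markers (4 measured, of which Cd79b changed by -1.34 but by -0.33 with normexp, and was not past the threshold there or with slide as a block) and of erythroid and platelet markers (4 measured, 0 past the threshold) were too small. The genes named were drawn from Mmp19, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with completely separated groups, leaving out clone and predicted names, and from each list up to 4 members past the threshold with the largest change, or up to 2 with the smallest p where none passed.

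Each slide held the knockout and the wild-type array of the same replicate number, so the replicate block and the slide block are 1 fit. Deviations from the group means correlated at 0.096, -0.021 and 0.210 within the 3 slides, so the arrays were not treated as pairs; slide is a batch that held both groups, and values with slide as a block and within slides are given. Alternatives covered normexp background correction (offset 50), quantile and cyclic loess normalization, the median or 75th percentile of probes well above background on all arrays, other filters on dim probes, the authors' log2 values, a trended robust prior, array weights and leaving out each array. The files held no mean signal, so normexp was run on the median signal. Its offset is added to every signal, which shrinks the log2 changes of dim probes. The 75th percentile over detected probes was added after the data were seen. Counts of alternatives hold some repeats. The replicate block and the slide block were counted apart, and the fit without saturated probes equals the main fit. For lists, the run without a filter and the run over all named genes on the array are also the same.

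The fit and the list test were tested on simulated data with the means and spreads of 24146 probes, comparing 3 arrays with 3. Of 50 probes each changed 2-fold, 4-fold, 8-fold and 16-fold, 1, 37, 47 and 49 were recovered, with 11 false calls among 146. A planted list of 30 genes shifted by 1 log2 unit was called, and 0 of 40 unchanged lists were. The simulated noise was independent between probes, so this could not show false list calls from genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.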

Results

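Gene expression was measured in cultured lung fibroblasts of mice that lacked Mmp19, a matrix metalloproteinase, and of wild-type mice. All animals had received bleomycin, a drug that injures the lung and is followed by fibrosis, at 0.08 units into the trachea, and fibroblasts were isolated on day 21 and incubated for 72 hours. Each group had 3 one-colour microarrays, which the series describes as coming from independent experiments. The study asked how Mmp19 bears on the expression profile of lung fibroblasts, so the design holds 1 comparison, knockout against wild type. The 75th percentile of the processed signal lay between 138 and 328 on the knockout arrays and between 190 and 290 on the wild-type arrays. Between 43.1% and 52.5% of spots were well above background on the knockout arrays, and between 44.6% and 54.5% on the wild-type arrays. The small number of arrays limits the precision of every value that follows. Wild-type replicate 2 stood apart from its group, with correlations of 0.939 and 0.960 with the other wild-type arrays, which correlated at 0.984 with each other. The knockout arrays correlated at 0.958 (replicates 1 and 2), 0.980 (1 and 3) and 0.986 (2 and 3). Arrays did not group by genotype alone: knockout replicate 2 and wild-type replicate 3 correlated at 0.963, above some pairs within each group. The labels give female sex and an age of 11 weeks for all animals. Xist, the RNA of the inactive X chromosome, was well above background on 3 of 3 knockout arrays and on 0 of 3 wild-type arrays, whereas the Y-linked Eif2s3y and Ddx3y were well above background on all 6 arrays. The scaled signals of Eif2s3y and Ddx3y were lower by 3.21 and 2.47 on the log2 scale in the knockout, with every knockout array below every wild-type array. They did not pass over all probes (limma adjusted p = 0.112 and 0.139), but both passed adjusted over the list of sex-linked genes alone (2 lower), and a difference in sex or in animals, if present, would run along with genotype in every change reported here.

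The targeted gene, Mmp19, was not well above background on any knockout array and was well above it on all 3 wild-type arrays. Its normalized log2 signal was -5.93 ± 0.65 (SD, n = 3) in knockout and -1.31 ± 1.20 (SD, n = 3) in wild-type cells, which is at least 5.33-fold lower in the knockout (limma adjusted p = 0.016). It was lower in the knockout on each of the 3 slides, each of which held 1 array of each group, and with slide as a block the adjusted p was 0.0271. Since the knockout signals lay at background, only the bound is given for its size. That bound holds for the processing used: with normexp the log2 change was -1.40 and did not pass. The Mmp19 call held in 14 of 18 alternatives, which count the slide block under both its names and a fit without saturated probes that equals the main fit. An exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. Mmp19 was read by a single probe, A_51_P269166, whose place relative to the deleted part of the gene is not given in the sources used here.

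In lung fibroblasts without Mmp19, some collagens, collagen processing enzymes, contractile genes, Wnt modulators and mesothelial markers were higher, and some interferon-induced genes were lower. As lists, these groups passed with a preset correlation between genes and not with an estimated one (adjusted p = 0.227, 0.260, 0.613, 0.333, 0.510 and 0.531 with an estimated correlation, in that order). The contractile list was also lost without wild-type replicate 1, and the interferon list did not shift on the second slide. Of 24214 probes tested, 1124 differed between the groups in the limma fit (adjusted p under 0.05), 697 higher and 427 lower in the knockout, with 5117 at an unadjusted p under 0.05. These probes named 598 genes, 412 higher and 186 lower, counting 1 probe per gene, and 362 of the probes carried no gene symbol here. In 594 of the 598 genes all knockout arrays lay on one side of all wild-type arrays, and so on the same side within each slide. The other 4 lacked a value on some array. Passing a test of 3 arrays against 3 makes such separation likely, so it is no separate support. Such separation held for 29.6% of all probes tested. Chance gives 10% for unselected probes. The filter also took in probes well above background on all arrays of only 1 group, which favours separation, so the 2 shares do not compare directly. The count with slide as a block was 385 probes, 228 higher and 157 lower, of which 348 were also in the fit without it; of 104 genes chosen to be named that passed, 52 also passed with it. Leaving out 1 array gave 107 probes without knockout replicate 3, 116 without wild-type replicate 3, between 421 and 536 without 3 others, and 1716 without wild-type replicate 2. The share of higher probes, 62.0%, depended on scaling and arrays: it was 51.9% when arrays were scaled to the probes detected on all arrays (608 higher and 563 lower), 48.8% without wild-type replicate 2 and 76.7% without wild-type replicate 3.

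**Figure D1:**
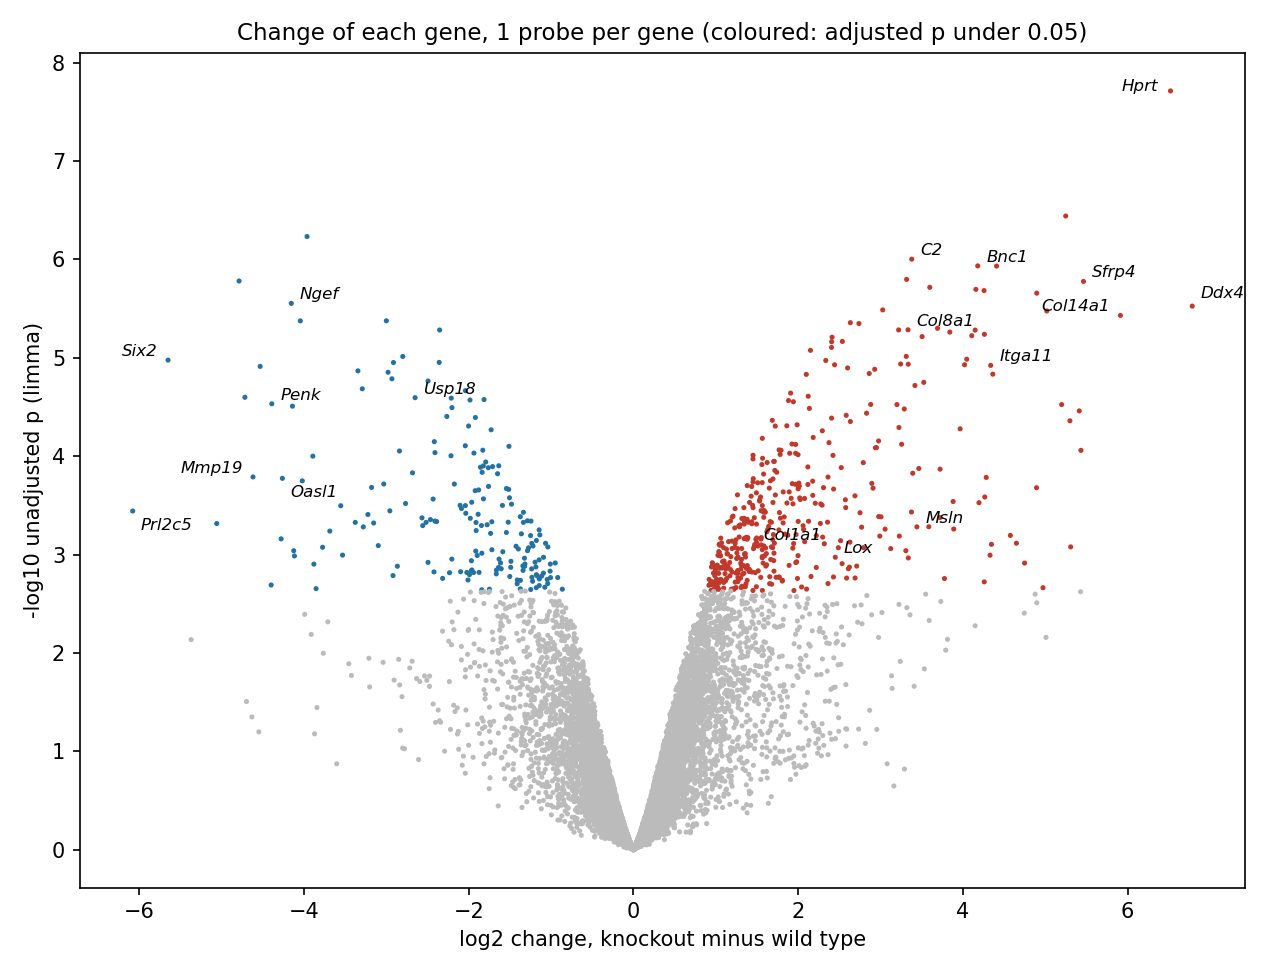
Each point is 1 gene, with the log2 change of its probe (knockout minus wild type, 3 arrays each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Coloured points passed an adjusted p of 0.05 (412 higher in red, 186 lower in blue), and Hprt had the smallest p.

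The largest rises included several genes that were not well above background on any wild-type array. Ddx4, a germ cell RNA helicase, was at least 38.8-fold higher in the knockout (adjusted p = 0.00314). Col28a1, a collagen chain, was at least 22.2-fold higher, Angpt4, an angiopoietin, at least 15.3-fold, and Sfrp4, a secreted Wnt-binding protein, at least 12-fold. Igsf23, Fgf21 and Xist were at least 8.75-fold, 7.96-fold and 7.41-fold higher. These bounds hold for the processing used: with normexp the log2 changes of the 7 genes ran from 1.55 (Fgf21, not past the threshold at 0.0541) to 3.21 (Ddx4), with Igsf23 at 1.62 and Xist at 1.72. Hprt, a purine salvage enzyme encoded on the X chromosome, was measured on all arrays and rose by 6.52 ± 0.23 log2 units (SE, n = 3 per group; adjusted p = 0.000469). Col14a1, a fibril-associated collagen, rose by 5.91 ± 0.45 on its brighter probe and by 0.69 on a dimmer one that did not pass. Mlana, Xlr4a and Smpd3 rose by 5.43 ± 0.67, 5.31 ± 0.94 and 4.97 ± 1.05, with Mlana and Xlr4a not past the threshold with slide as a block (0.0527 and 0.0933). Smpd3 passed in only 6 of 18 alternatives, against 15 of 19 for Mlana and 11 of 18 for Xlr4a.

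Among the largest falls, Six2, a homeobox transcription factor, was at least 14.2-fold lower (adjusted p = 0.00439), and Mir17hg, the host transcript of the miR-17-92 microRNA cluster, at least 14.1-fold lower; both were not well above background on any knockout array. Wnt10a, a Wnt ligand, was at least 7.63-fold lower, but passed in only 3 of 18 alternatives. With normexp the log2 changes of Six2, Mir17hg and Wnt10a were -2.30, -2.16 and -1.58, the last 2 not past the threshold (0.0505 and 0.170). Prl2c5, a prolactin family member, changed by -6.08 ± 0.94 log2 units (SE, n = 3 per group), Stac2 by -5.06 ± 0.82, Zfp979 by -4.79 ± 0.32 and Olfr224 by -4.53 ± 0.41. Penk, the precursor of enkephalin peptides, changed by -4.39 ± 0.45 and Ngef by -4.15 ± 0.30. Prl2c5, Xlr4a, Zfp979 and Olfr224 belong to families of near-identical genes, so which member their probes read is uncertain. Olfr224 was well above background on only 1 knockout array, and its weakest change among the alternatives was -2.67. Of the 24 genes of largest change, Mmp19 among them, 20 also passed with slide as a block, and Mlana, Xlr4a, Stac2 (0.0524) and Wnt10a (0.0906) did not.

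**Figure D2:**
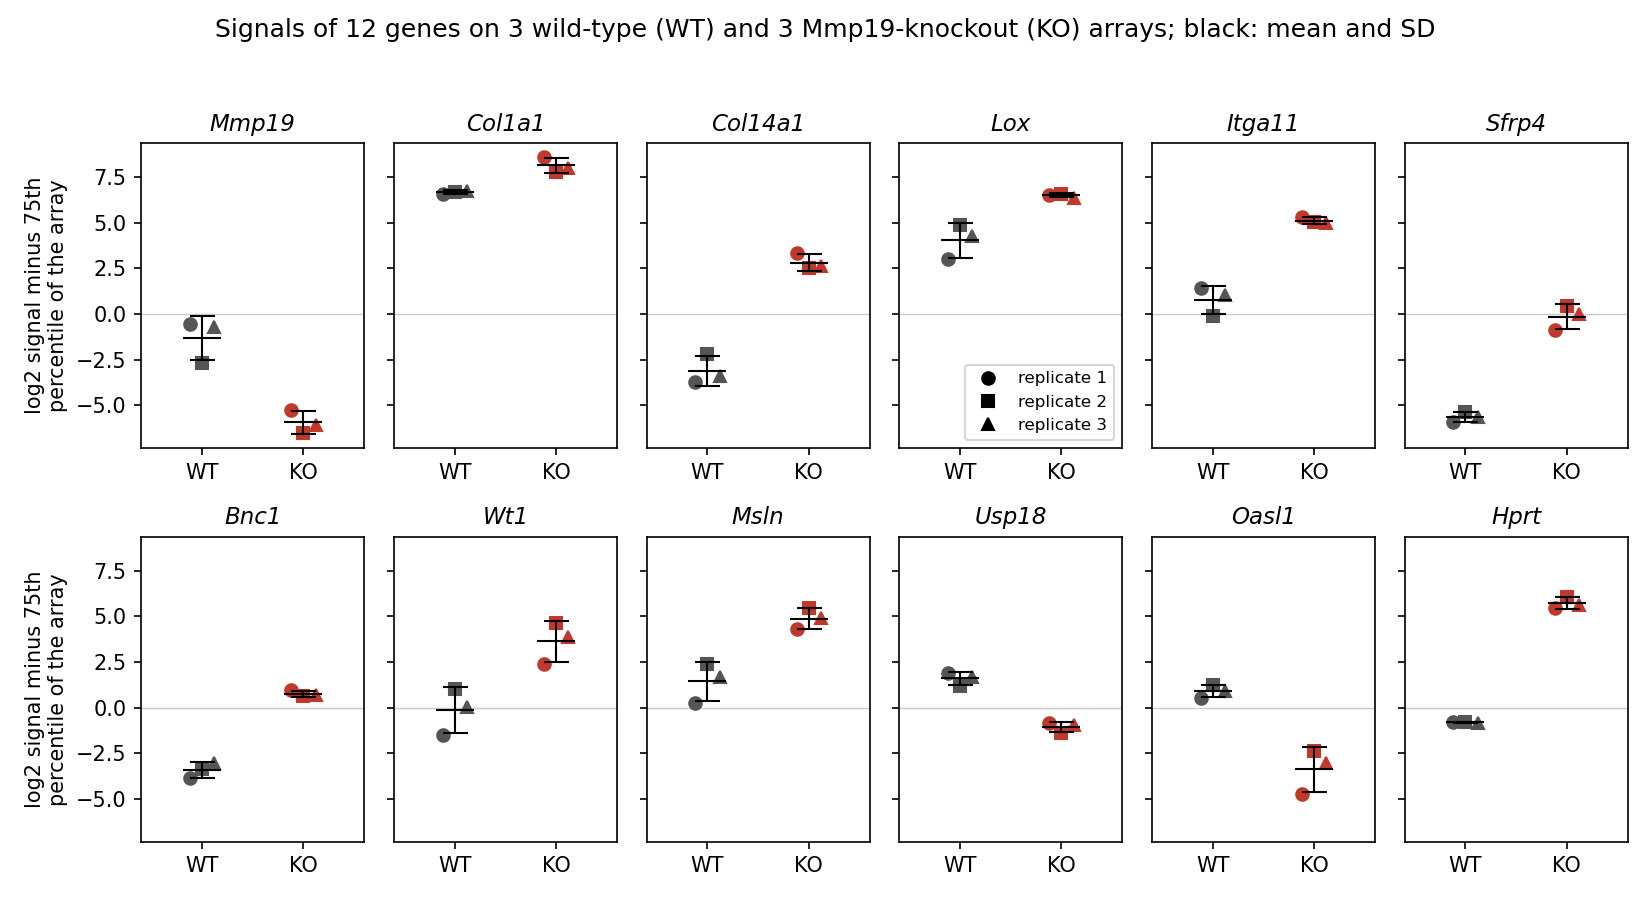
Signals of 12 genes on each array, as log2 signal minus the 75th percentile of the array; symbols mark replicates, and black bars give the mean and SD of 3 arrays per group. Knockout and wild-type arrays did not overlap for any of these genes, with Mmp19 at -5.93 in knockout and -1.31 in wild-type cells.

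Several collagen genes rose in the knockout cells. Of 12 measured fibrillar and associated collagens, 5 rose and 0 fell, with a median log2 change of 1.26 over the list. Besides Col14a1 these were Col8a1 (+3.33 ± 0.26), Col11a1 (+1.93 ± 0.27) and the 2 chains of type I collagen, Col1a1 (+1.47 ± 0.26) and Col1a2 (+1.25 ± 0.25). Of 23 measured collagen processing and crosslinking genes 5 rose and 0 fell, among them the crosslinking oxidases Lox (+2.45 ± 0.45) and Loxl1 (+1.81 ± 0.37), the prolyl hydroxylase subunit P4ha1 (+1.69 ± 0.30) and the collagen uptake receptor Mrc2 (+2.22 ± 0.38). Adjusted over the list alone, 10 collagens and 14 processing genes passed. The camera test gave adjusted p = 5.32e-06 for the collagens and 2.73e-06 for the processing genes, and adjusted p = 0.227 and 0.260 with an estimated correlation. The values with slide as a block were 9.26e-06 and 4.2e-06, and the medians within slides ran from 1.20 to 1.76 and from 0.79 to 1.38. Gene by gene, Col14a1 and Col8a1 kept their calls with slide as a block, while Col11a1, Col1a1 and Col1a2 (adjusted p = 0.0706, 0.0845 and 0.0944) and Lox, Loxl1, P4ha1 and Mrc2 (0.0723, 0.117, 0.0872 and 0.0750) did not.

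Some genes of 5 other matrix lists also passed. Of 18 basement membrane genes 4 rose, led by nidogen 2, Nid2 (+4.05 ± 0.36), with the laminin chain Lama5 (+2.13 ± 0.34) and the type IV collagen chains Col4a6 (+1.92 ± 0.23) and Col4a5 (+1.08 ± 0.21). Of 21 proteoglycan and hyaluronan genes 3 rose, the small leucine-rich proteoglycans Podn (+4.02 ± 0.36), Ogn (+3.84 ± 0.31) and Fmod (+3.32 ± 0.22). Fmod was well above background on only 1 wild-type array, and its weakest change among the alternatives was 1.92. Of 24 matrix glycoprotein and elastic fibre genes only the thrombospondin gene Thbs1 passed (+1.13 ± 0.20), although 21 changes were positive. Of 24 metalloproteinases other than Mmp19, 2 rose, the membrane-bound collagenase Mmp14 (+1.62 ± 0.27) and Adam23 (+1.62 ± 0.21). Of 20 protease inhibitor and plasminogen genes, 3 rose, namely the urokinase gene Plau (+2.36 ± 0.32), Serping1 and Ctsb, and Serpinb2 fell (-3.85 ± 0.81). Adjusted over the list alone, the counts of higher genes in these 5 lists were 8, 4, 1, 6 and 7, with 1, 0, 0, 0 and 1 lower. Camera adjusted p values were 0.017, 0.0216, 0.0216, 0.020 and 0.0136 in the same order, and adjusted p = 0.403, 0.613, 0.403, 0.587 and 0.403 with an estimated correlation. They were 0.0301, 0.0301, 0.00983, 0.0128 and 0.0105 with slide as a block, and every within-slide median was positive. Among the genes named from these lists, Lama5, Col4a5, Thbs1, Adam23, Plau, Ctsb and Serpinb2 lost their calls with that block. The metalloproteinase call was lost without wild-type replicate 2 (adjusted p = 0.447), the proteoglycan call without knockout replicate 2 (0.102) and the protease inhibitor call without wild-type replicate 1 (0.110).

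Some contractile and signalling genes also passed, most of them higher in the knockout. The smooth muscle actin gene Acta2, a usual marker of myofibroblasts, did not pass. Of 31 myofibroblast and smooth muscle contractile genes 5 rose (11 adjusted over the list alone) and 0 fell, with Itga11, a collagen-binding integrin, at +4.34 ± 0.39, Itga8 at +3.29 ± 0.35, smooth muscle myosin Myh11 at +2.98 ± 0.35 and desmin, Des, at +2.49 ± 0.44. Of 31 Wnt pathway genes 8 rose and 0 fell (10 higher and 1 lower adjusted over the list alone; Wnt10a, which fell, is not on this list), including Sfrp4, the R-spondin Rspo1 (+3.72 ± 0.59), Ccn5 (+2.53 ± 0.48) and the receptor Fzd2 (+1.71 ± 0.22). Of 40 growth factor and receptor genes 3 rose and 1 fell (5 and 1 adjusted over the list alone), namely Ccn3 (+4.26 ± 0.29), Vegfd (+3.46 ± 0.45), Fgf9 (+2.43 ± 0.34) and Pgf (-2.43 ± 0.32). Pgf had no value on wild-type replicate 2. Des and Fgf9 were well above background on only 1 wild-type array, and their weakest changes among the alternatives were 1.04 and 0.90. Of 25 SRF and immediate early genes 2 rose (4 adjusted over the list alone), Fos (+2.43 ± 0.49) and Amotl2 (+1.30 ± 0.25). Of 24 lung fibroblast markers 3 rose (10 adjusted over the list alone), with dermatopontin, Dpt, at +2.91 ± 0.41 beside the type I collagen genes. Camera adjusted p values for these 5 lists were 0.00174, 0.0091, 0.0387, 0.00576 and 0.0091, and adjusted p = 0.613, 0.333, 0.403, 0.629 and 0.403 with an estimated correlation. With slide as a block they were 0.00184, 0.00983, 0.0301, 0.0091 and 0.00983, and every within-slide median was positive. Ccn5, Fzd2, Pgf, Fos and Amotl2 lost their calls with that block. The contractile call was lost without wild-type replicate 1 (adjusted p = 0.119), and the immediate early call without wild-type replicate 2 (0.0636). The growth factor call was lost in 4 of the 6 fits that left out 1 array, without knockout replicate 2 and without each wild-type replicate in turn (adjusted p = 0.0594, 0.058, 0.0836 and 0.0546).

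Mesothelial markers, genes typical of the cell layer that lines the lung surface, had the highest median change of the tested lists, 3.13 on the log2 scale. It was 1.94 without wild-type replicate 1, 2.34 with normexp and 1.64 over genes well above background on all 6 arrays. Of 19 measured, 6 rose and 0 fell (10 and 0 adjusted over the list alone): Upk3b (+4.75 ± 0.90), Lrrn4 (+4.26 ± 0.87), Bnc1 (+4.18 ± 0.27), the transcription factor Wt1 (+3.78 ± 0.76), Rspo1 and mesothelin, Msln (+3.44 ± 0.56). The camera adjusted p was 0.000136, and adjusted p = 0.510 with an estimated correlation; with slide as a block it was 9e-06, and the medians within slides were 3.45, 3.06 and 2.40. Of the 6 genes only Lrrn4 lost its call with that block (0.0528). Lrrn4 passed in only 6 of 18 alternatives and Wt1 in 9 of 19, against 13 of 18 for Upk3b, 14 of 19 for Rspo1 and 18 of 18 for Bnc1. Of these 19 genes 8 also stood on another list and 12 were well above background on all wild-type arrays. Bnc1 was well above background on only 1 wild-type array, and its weakest change among the alternatives was 2.34. Markers of the other cell types did not shift as lists: camera adjusted p was 0.299 for 24 lung epithelial, 0.757 for 17 macrophage, 0.862 for 15 endothelial, 0.757 for 9 T and NK cell, 0.0607 for 8 granulocyte and mast cell, 0.646 for 9 muscle and 0.733 for 6 Schwann and neural markers, although Eng, Tnni3 and Mbp rose among the endothelial, muscle and Schwann markers, calls that were lost with slide as a block. The 16 pericyte and vascular smooth muscle markers, 3 of which rose (Myh11, Gucy1a1 at +2.79 ± 0.50, and Des), had an adjusted p of 0.0556, and 0.0419 with slide as a block, and adjusted p = 0.587 with an estimated correlation. Of 23 alternatives the pericyte list passed in 9, the granulocyte and mast cell list in 3 and the lung epithelial list in 1.

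Some genes of lipid synthesis, stress responses and complement also rose. Of 31 cholesterol and fatty acid synthesis genes 8 rose and 0 fell (18 and 0 adjusted over the list alone), including the cholesterol exporter Abca1 (+2.27 ± 0.37), the sterol sensor partner Insig1 (+1.83 ± 0.29) and the fatty acid desaturases Fads2 (+1.78 ± 0.28) and Fads1 (+1.67 ± 0.31). Of 32 ER stress and amino acid response genes 3 rose (10 adjusted over the list alone), Chac1 (+1.97 ± 0.33), Vldlr (+1.23 ± 0.22) and Trib3. Of 34 autophagy and lysosome genes 2 rose and 1 fell (3 and 1 adjusted over the list alone): the transcription factor Tfeb (+1.58 ± 0.24), the autophagosome protein gene Map1lc3b (+1.17 ± 0.23) and the protease gene Atg4c (-1.71 ± 0.22). Of 13 complement genes 5 rose (5 adjusted over the list alone), with C2 at +3.38 ± 0.21, Cfi at +2.08 ± 0.31, Serping1 at +1.97 ± 0.24 and C4b at +1.73 ± 0.35. Cfi was well above background on only 1 wild-type array, and its weakest change among the alternatives was 0.89. Camera adjusted p values for these 4 lists were 5.32e-06, 0.000609, 0.00969 and 0.0285, and adjusted p = 0.346, 0.510, 0.587 and 0.403 with an estimated correlation. With slide as a block the first 3 were 1.64e-05, 0.00179 and 0.00983, while the complement call was lost (0.0617), as it was without wild-type replicate 2 (0.205) and without knockout replicate 1 (0.054). Without wild-type replicate 2 the median of the complement genes was -0.05. All within-slide medians of the 4 lists were positive, and those of the complement list were 0.15, 2.15 and 0.23. Fads1, Atg4c, C2, Cfi and Serping1 kept their calls with slide as a block, and the other genes named from these lists did not.

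Some interferon-induced genes were lower in the knockout cells. Of 33 measured, 6 fell and 0 rose (12 and 1 adjusted over the list alone), and 25 changes were negative. Oasl1 changed by -4.26 ± 0.58, Usp18, which removes the ubiquitin-like ISG15 from proteins, by -2.65 ± 0.27, Oas1a by -2.21 ± 0.41 and Ifi44 by -2.02 ± 0.40 (SE, n = 3 per group). The camera adjusted p was 8.94e-06, and adjusted p = 0.531 with an estimated correlation. With slide as a block it was 1.22e-05, but the medians within slides were -1.30, 0.07 and -0.93, so the shift of the list as a whole was absent from the second slide. The 34 DNA replication and G1/S genes had a median of -0.44 and an adjusted p of 0.017 (0.017 with slide as a block, and adjusted p = 0.841 with an estimated correlation), yet 1 gene rose, the primase subunit Prim2 (+3.52 ± 0.34), and 1 fell, E2f2 (-2.32 ± 0.47). The medians of that list within slides were -1.55, 1.06 and -0.89, and its call was lost without wild-type replicate 1 (median -0.03, adjusted p = 0.561) and without wild-type replicate 3 (0.0560), while the median was -1.06 without wild-type replicate 2. Among 30 cytokines and chemokines the median was -1.03 (adjusted p = 0.0233, 0.0412 with slide as a block, and adjusted p = 0.791 with an estimated correlation), with within-slide medians of -2.43, 0.80 and -1.35. No cytokine fell past the threshold, and the one gene that passed, the receptor subunit Il6st, rose (+2.01 ± 0.28). The cytokine list call was lost without knockout replicate 1 (0.086) and without wild-type replicate 1 (median -0.52, adjusted p = 0.208), and the median was -1.71 without wild-type replicate 2. It was also lost with fry (0.741), quantile (0.0539) and cyclic loess normalization (0.0518), scaling to the 75th percentile of detected probes (0.0873) and the authors' values (0.0835). Oas1a, E2f2 and Il6st lost their calls with slide as a block.

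**Figure D3:**
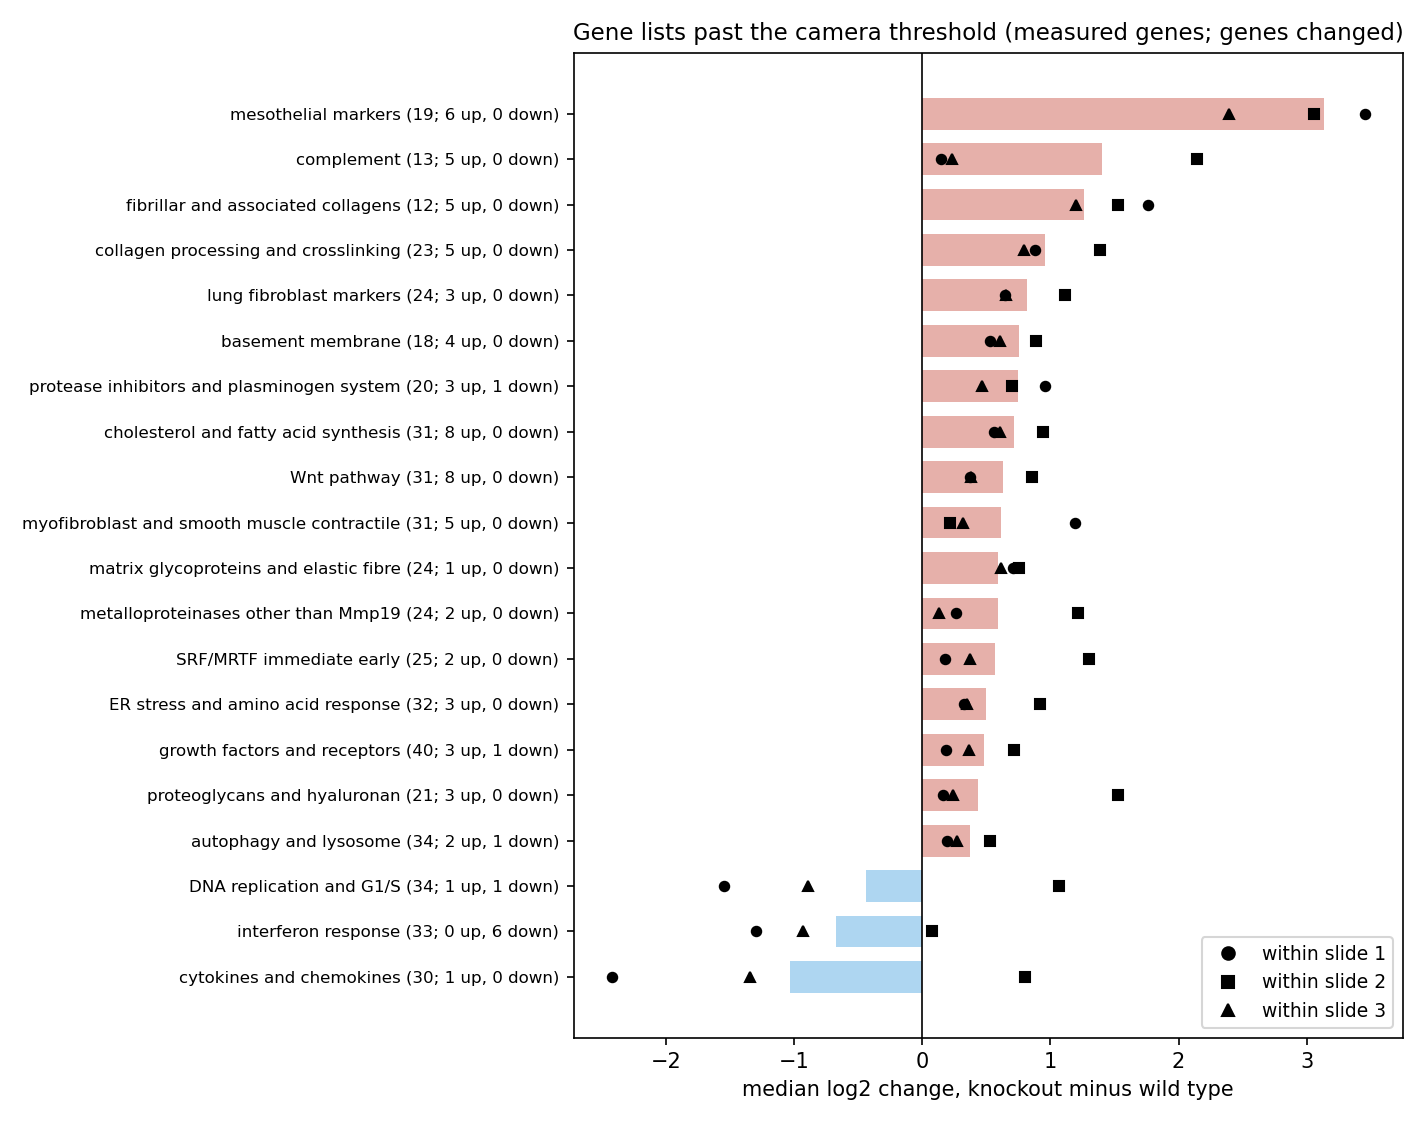
Median log2 change (knockout minus wild type) of the 20 gene lists that passed the camera test, as bars, with the medians within each of the 3 slides as symbols; labels give the number of genes measured and the numbers that rose and fell. In 17 lists all 3 slides lay on the same side, and in the 3 lists with negative medians the second slide lay on the other side.

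The other lists did not pass the camera test, with adjusted p between 0.0556 and 0.862. Among 39 TGF-beta pathway genes 4 rose and 1 fell (adjusted p = 0.624): the activin antagonist Fst changed by -2.91 ± 0.26, and Bmp4 (+1.97 ± 0.24), Eng (+1.22 ± 0.26) and Tgfbr2 (+1.21 ± 0.26) were among the rises. Of 31 antioxidant genes 5 rose, including Aldh1a1 (+2.63 ± 0.46), Gsta4 and Gclm, while Nqo1 fell (-1.54 ± 0.26; list adjusted p = 0.169). Of 21 lipofibroblast and adipogenic genes 4 rose, including Lrrn4, Lpl (+2.22 ± 0.43), Npr3 and Limch1, and Plin2 fell (adjusted p = 0.0836). Of 32 mitosis genes 0 passed (adjusted p = 0.160), and the smallest p belonged to Ndc80 (+0.98 ± 0.57) and Cenpe (-0.91 ± 0.58). The medians of the mitosis list within slides were -1.72, 1.96 and -0.73. That list passed in 2 of 23 alternatives, and its median ran from -1.01 to 0.42 over them. Of 44 adhesion, migration and integrin genes 2 rose, Ezr and Itga7 (0.776), and of 17 reference genes only Hprt passed (0.624). Mesenchymal transcription factors (0.160), Hox genes (0.338), glycolysis and hypoxia genes (0.237), p53 and senescence genes (0.757), prostaglandin genes (0.624) and antigen presentation genes (0.624) did not shift as lists either. The last 4 lists held 1 rise each, of Ndrg1, Gadd45a, Ephx2 and H2-DMb1 in that order. Of the genes named from these lists only Fst, Aldh1a1, Gsta4, Lpl and Hprt kept their calls with slide as a block.

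Camera called 20 of 40 lists with a preset correlation and 0 with an estimated one, so the list calls depend on that choice. A higher correlation does not account for the loss in every list. The estimated value was -0.019 for the collagens and -0.023 for the Wnt genes, below the preset 0.01. For the collagens the unadjusted camera p still went from 2.98e-07 to 0.00569. Estimating the correlation also lowers the degrees of freedom of the test to those of the arrays. The values with an estimated correlation thus do not measure the effect of correlation alone. With slide as a block 19 of the 20 calls held. The fry test dropped the interferon (adjusted p = 0.115), contractile (0.0844), immediate early (0.130), autophagy (0.0844), metalloproteinase (0.0922), G1/S (0.807) and cytokine (0.741) lists. Of 23 alternatives the call held in 15 for cytokines, 16 for complement, 17 for growth factors, 19 for metalloproteinases and for G1/S genes, and 20 or more for each other list. Some of the 23 repeat each other or the main fit, so these counts overstate how many separate checks were made.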

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

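All alternatives but the 75th percentile of detected probes were chosen before the data were examined. The count of changed probes, 1124, was 633 with normexp, 113 with no filter, 650 for probes well above background on all 6 arrays, 385 with the replicate block (equal to the slide block; 348 probes shared with the fit without it), 5069 with array weights, 2219 at an adjusted p under 0.10 and 112 with the ordinary unmoderated test. Leaving out 1 array gave 481, 536 and 107 probes without knockout replicates 1, 2 and 3, and 421, 1716 and 116 without wild-type replicates 1, 2 and 3. Without a filter 55681 probes were tested. Leaving out an array leaves fewer samples, but the count rose without wild-type replicate 2, so which array was left out mattered too. For the other alternatives the cause was not tested. The other scalings, the authors' log2 values, the trended robust prior and the 2-fold threshold gave counts within 1.5 times, from 985 to 1171. Scaling to the 75th percentile of detected probes moved the median change of all tested probes by -0.117, and the authors' values by -0.105. Mmp19 stayed lower throughout, at an adjusted p from 0.000267 to 0.0900. It was not past the threshold with normexp (a change of -1.40), with no filter (-4.62, adjusted p = 0.0551) or without knockout or wild-type replicate 3, and changes ran from -5.31 to -4.24 when 1 array was left out. Since its knockout signals lay at background, these changes give the direction and not the size. With probes well above background on all 6 arrays Mmp19 had no value. The number of shifted lists, 20, was 0 with an estimated correlation, 14 with fry, 20 with the replicate block, 16 to 21 without 1 array and 17 to 22 otherwise. No called gene among those named changed sign, and no called list did in the camera test, though the median of the complement list was -0.05 without wild-type replicate 2; of 103 called genes named beside Mmp19, 51 passed with the replicate block, 29 with no filter and between 24 and 97 without 1 array. Same-numbered arrays did not all correlate best with each other. No spot was saturated, so leaving out saturated probes moved nothing. Signal over background limits the folds of genes that were dim in 1 group.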

Other observations

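The tests of the mesothelial markers and of the sex-linked signals were chosen only after these results were seen, and the genes of the next paragraph were picked after their values were seen. The test that compared parts of each chromosome was written after the chromosome medians had been seen, but before its own result.

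Several genes outside the lists fixed beforehand had changes as large as those of the matrix genes. Rnf17, a tudor protein of germ cells that lacked a value on 1 wild-type array, and Hils1, a histone of spermatids, were not well above background on any wild-type array and were at least 4.36-fold and 3.80-fold higher in the knockout (limma adjusted p = 0.00469 and 0.00356), beside the rise of Ddx4. The X-linked Xlr3b rose by 4.19 ± 0.63 log2 units (SE, n = 3 per group) and Xlr3a by 3.38 ± 0.52, in a family of near-identical genes whose probes may not be told apart, and both lost the threshold with slide as a block (0.0739 and 0.0738). Abi3bp, a matrix protein gene, was at least 11.4-fold higher (0.0527 with slide as a block). The transcription factor Irx2 was at least 8.72-fold lower (0.0532 with slide as a block), and Nkx6-1 and Isl1 changed by -2.93 ± 0.28 and -2.57 ± 0.41. Ppargc1a, a coactivator of mitochondrial genes, was at least 3.51-fold lower. The smooth muscle actin gene Acta2, a usual marker of myofibroblasts, did not pass (+0.83 ± 0.69, adjusted p = 0.530), with normalized signals of 8.35 ± 0.13 (SD) in knockout and 7.52 ± 1.51 in wild-type cells.

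None of the 9 other splits of the 6 arrays into 3 and 3 gave a changed probe, against 1124 in the real split. So 1 of 10 splits gave as many, which is too few splits for a share under 0.05. Each other split put arrays of both genotypes in each group. That adds any genotype difference to the spread within groups and makes calls of single probes unlikely from the start. For the gene lists the real split gave 20 and the others from 0 to 16, again 1 of 10. The split that grouped knockout replicates 1 and 3 with wild-type replicate 2 gave 16, so a preset correlation also gave list calls for splits that mix the genotypes. Such splits still hold part of the genotype difference, and directions were not compared. The 16 calls therefore cannot show which differences between the arrays they followed.

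The median change of the mesothelial markers was 3.13 (1.94 without wild-type replicate 1), with 6 of 19 genes past the threshold and adjusted p = 0.510 for the list with an estimated correlation. The rise hardly depended on brightness-dependent scaling: relative to all genes, the smaller median under quantile and cyclic loess scaling was 0.984 of the value reported. An offset of whole arrays cancels in that measure, so the comparison could not test it. Markers of other cell types did not rise alike: the mesothelial median lay 3.16 above that of 93 markers of other non-mesenchymal cell types (-0.02, SD 0.79). Cell types absent from the cultures could not rise, so this cannot exclude a lower share of fibroblasts. The lung fibroblast markers had a median change of 0.82. A larger share of mesothelial cells would raise their abundant transcripts alike, yet keratin 19 changed by -0.28 ± 0.42 and keratin 8 by -0.02 ± 0.24, against 2.55 ± 0.70 for the bright keratin 18 (adjusted p = 0.0941, higher on all 3 slides), and the middle 50% of the list ran from 0.23 to 3.98. The first version of this test counted both keratins as evidence against that account; a condition on brightness was added after its result was seen, and since keratin 8 lay at percentile 3.53 of the tested probes (keratin 19 at 28.8), the account is left open, as is a change within fibroblasts, which may also account for the rise and was not tested.

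The sex-linked signals did not follow the labels, which give female for all animals. Xist was well above background on 0 of 3 wild-type arrays, while Eif2s3y had a mean log2 signal of 11.4 and Ddx3y of 8.89 there, as RNA of male cells would give, but the Y-linked Kdm5d and Usp9y were not well above background on any array, and 2 Uty probes were so on only 1 of 3 wild-type arrays. In the knockout arrays both Xist (6.95) and Eif2s3y (8.17) were present. Binding of the Y-linked probe to its X-linked copy is argued against, because log2 Eif2s3y minus log2 Eif2s3x varied by 4.44 over the 3 knockout arrays, where a constant share would keep it level; a mixture of male and female cells or animals in the knockout cultures may explain the pair of signals, and was not tested. Hprt, also X-linked, had a log2 signal from 6.79 to 7.34 in wild-type and from 12.6 to 14.4 in knockout cells, and no explanation of it was tested.

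Whole chromosomes differed slightly between the groups. Relative to all genes, the median change was -0.25 over 792 genes of chromosome 4, with 30 genes lower and 12 higher, and 0.19 over 426 genes of chromosome 14, with 18 higher and 3 lower; their camera adjusted p values were 1.26e-05 and 0.0122, and adjusted p = 0.9999 for both with an estimated correlation. Medians of the genes before and after the midpoint of each of 20 chromosomes correlated at r = 0.854 (permutation p = 3e-05; rho = 0.690, permutation p = 0.00105; r = 0.740 without chromosomes 4 and 19, whose first parts lay farthest from the median, and with chromosome 14 kept), as a difference in chromosome copy number between the cultures would give. A trend with brightness is argued against, since removing it left the spread of the chromosome medians at 1.01 of its value. Copy number is thus a candidate explanation that DNA measurements could test, and base composition of the probes was not tested.

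In the knockout, DNA of another strain around the targeted gene could change nearby genes. Of 50 tested genes next to Mmp19 in gene order, 40 on one side and 10 on the other, 1 passed (Itga7, 2%, with an upper confidence bound of 10.6%), against 4.80% of 12415 other genes (Fisher exact two-sided p = 0.733), and that bound is too wide to decide. The count takes the brightest probe of each gene, and a second probe of the neighbour Rnf41 also passed (-1.59, adjusted p = 0.0125).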
